A study of Mus musculus with 21 samples.

How the data were processed

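Gene expression was measured with a NanoString PanCancer panel of 750 mouse genes, per the series description, in 21 libraries of total RNA extracted with TRIzol from whole tumors, per the labels' protocols. The authors deposited a matrix of normalized values for all libraries and a file per library. The deposited values are signal values on a linear scale, and the software, the control probes and the scaling set used to make them are not given in the sources used here. Housekeeping, positive and negative control probes were not used here, since the files list endogenous probes. The columns that the file headers name as gene name and class are swapped, which was checked on the values. The per-library files equalled the matrix within their rounding to 1 decimal at every probe and were used for that check alone.

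In each library the deposited values were whole multiples of a step that differed between libraries, from 0.65 to 1.41, so that they are molecule counts times a factor per library. The steps made 99.6% to 100% of the values whole within 0.1 of a step. The counts so recovered summed to between 256573 and 763976 per library, and they set the counting precision of low probes. In some libraries the lowest value is above 1 count, so a common multiple of their counts cannot be excluded. No value was 0 and 2 cells were blank, both for Hif1a. Agonist replicates 6, 7 and 8 were written with 2 decimals and the other 18 libraries with more. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per degree of freedom being 6.77. Of 750 accessions 727 matched the reference table of the GRCm38.p6 assembly, 9 of them under another symbol (Tmem173 is Sting1 there), and the files' names were kept. No genome build is named in the sources used here, and no coordinates are given.

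The design fixed before the data were examined assumed raw counts with control probes and an edgeR main test, and named limma on log2 values for files without them. Limma was therefore the main test. Values were taken as log2(value + 1), so fold changes of low genes are understated. A probe was tested if its value was at least 20 in at least 4 libraries, in place of the planned filter on negative controls, which left 689 probes. Genes high only in agonist libraries can pass this filter, which favors calls of higher there. A linear model with a mean for each of the 3 groups was fitted to all 21 libraries (limma 3.58.1, eBayes with trend and robust), with 3 two-sided contrasts and Benjamini-Hochberg adjustment over genes within a contrast at 0.05. The replicate numbers in the titles did not enter the fit. Adjusted p-values in the text are limma's for genes and fry's for lists, unless another test is named.

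The 30 gene lists, 17 of pathways and 13 of cell types, were fixed beforehand. The muscle list had no gene on the panel and 29 lists had at least 3 tested genes. Lists were tested with fry, which asks whether the genes of a list move on balance in a direction and does not compare lists with each other, with adjustment over the lists within a contrast. Camera, which compares a list with the other genes, was run with a preset correlation of 0.01 and with an estimated correlation. With the preset the calls were T cell markers (higher), monocyte and neutrophil chemokines and proliferation genes (lower) after agonist, interferon-stimulated and neutrophil genes (lower) under deficiency, and interferon-stimulated genes, T cell markers (higher) and proliferation genes (lower) in the third comparison. None of these held with an estimated correlation. Lists overlap, so their results are not independent.

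The genes named in the text follow a rule fixed beforehand. Tmem173 always came first. For the agonist comparison the 12 highest and 12 lowest fold changes among genes past the threshold with a mean value of at least 50 in the higher group were eligible, and 8 and 8 for the others. Up to 4 members of each list with the smallest adjusted p were eligible, or up to 2 of the most abundant where fewer than 2 passed. This made 117, 66 and 117 genes in the 3 comparisons eligible, of which the text names 58, 24 and 37, a part chosen after values were seen; some eligible genes are not reported here. Of the eligible genes past the threshold, 117, 12 and 117, the direction turned with TMM scaling in 17, 0 and 11, of which the text names 9, 0 and 3. With TMM and without agonist replicates 6 to 8 it turned in 25, 0 and 16, of which the text names 9, 0 and 4. Probes of the Klra, Ifna and H2-Q families were treated as uncertain.

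Outliers within a group were sought with Dixon's ratio, for genes on the log2 scale and for Tmem173 also without the logarithm. Library measures were compared with exact permutation tests (scipy 1.17.1), 12 in all. A list score is the mean log2 value of a list's tested genes in a library minus the wild-type sham mean. The tests were checked on simulated data of 688 genes with 200 changed, in 5 runs. For the agonist comparison 60% of changes of 1 log2 unit and 95.7% of changes of 2 were recovered with 3.2% false calls. For STING deficiency these were 47.3% and 91.5% with 2.53%, and for the third comparison 43.2% and 89.7% with 3.78%. The simulated genes were independent, with the same dispersion in all groups and as many rises as falls. The real libraries differ in these points, so these rates may not hold for them. Alternatives tried were TMM (edgeR 4.0.16), median-of-ratios and total-count scaling of the recovered counts, no filter, DESeq2 1.42.0 and edgeR's quasi-likelihood test on the recovered counts, fits of the compared groups alone, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were edgeR's test, a filter at 50, a floor at 20, a pseudocount of 10, leaving out the 3 libraries with 2 decimals, the same with TMM scaling, and both again with the filter applied anew to the remaining libraries (597 genes). The filter at 20 in 4 libraries was also set after the data were examined. Where the 3 libraries were left out, the text leads with the fixed 689 genes, so that 1 choice changes at a time; this form was picked after both had been computed, and both are given. Python 3.11.15 and R 4.3.3 were used.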

Results

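The series measured 750 immune and tumor microenvironment genes in whole tumors of mice. Lewis lung carcinoma (LLC) cells, a mouse lung cancer line, were implanted in the flank of wild-type C57BL/6 mice or of mice homozygous for the goldenticket allele of Tmem173, the gene of the cytosolic DNA sensing adaptor STING. The goldenticket allele is a point mutation that leaves no working STING protein in the host, while the implanted tumor cells keep their own copy of the gene. Established tumors were injected with saline (sham) or with a STING agonist, which the series description names as cGAMP, the dinucleotide that activates STING. Total RNA of the whole tumor was counted on a NanoString panel, which counts RNA molecules with barcoded probes and no amplification. The labels give the tissue as lung although the growth protocol describes flank tumors.

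The 21 libraries fall into 3 groups, 9 from wild-type sham tumors, 8 from wild-type agonist tumors and 4 from STING-deficient sham tumors. No group of STING-deficient hosts with agonist was analysed here, so whether the agonist response needs host STING was not tested. The labels number the libraries without saying that each came from a separate mouse, so p-values measure the spread between these samples. The whole counts recovered behind the deposited values add up to between 256573 and 763976 molecules per library. The deposited scaled values summed to 269176 ± 19160 (SD, n = 9) in wild-type sham, 472376 ± 200365 (n = 8) in wild-type agonist and 255099 ± 31777 (n = 4) in STING-deficient sham libraries. The scaled totals of agonist libraries were higher than those of wild-type sham libraries (two-sided exact permutation p = 0.00197, adjusted p = 0.0111 over 12 comparisons of library measures). The recovered totals before scaling, 302789 ± 41064 and 418457 ± 163570, had an exact permutation p of 0.0368 (adjusted p = 0.0552). The factor that turns counts into scaled values was itself higher in agonist libraries, 1.12 ± 0.14 against 0.90 ± 0.14 (exact permutation p = 0.00461, adjusted p = 0.0111). The median probe was lower in STING-deficient than in wild-type sham libraries, 47.2 ± 10.5 against 64.2 ± 5.31 (exact permutation p = 0.0112, adjusted p = 0.0224).

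Tmem173 itself was present in every library. Its mean scaled value was 54.2 ± 11.1 (SD, n = 9) in wild-type sham, 115 ± 74.2 (n = 8) in wild-type agonist and 50.4 ± 12.8 (n = 4) in STING-deficient sham tumors. The difference between genotypes under sham was -0.11 ± 0.36 on the log2 scale (SE, adjusted p = 0.935), and a point mutation need not change the transcript, so this probe does not check the genotype labels. Tmem173 was higher after agonist than in wild-type sham by 0.85 ± 0.29 (adjusted p = 0.0156), in 7 of 8 libraries above the sham mean, but at -0.01 (adjusted p = 0.971) with TMM scaling, which sets each library against the bulk of the panel.

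The first comparison asks what intratumoral STING agonist changed in wild-type hosts. Most of the panel rose under the authors' scaling, with 71.1% of the tested genes and 27 of 29 lists higher. Genes of T cells, NK cells and cytotoxic effectors were among these, as were T cell attracting chemokines, complement genes and interferon-stimulated genes. The complement and interferon-stimulated lists did not pass with TMM scaling (fry adjusted p = 0.198 and 0.187). The T cell marker list was 2.84-fold higher by its median gene, with 14 of 15 tested members past the threshold, and the NK cell list 2.88-fold higher with 11 of 12. Cytotoxic effector genes rose in 12 of 12 cases with a median of 2.84-fold. With TMM scaling 7 of 15 T cell, 4 of 12 NK cell and 5 of 12 cytotoxic genes were higher. Without the agonist libraries written with 2 decimals these counts were 1, 0 and 0 under the authors' scaling. Ccl4, a chemokine that draws T cells and monocytes, had the largest rise of the genes named here, from 37.9 ± 14.1 (SD, n = 9) in sham to 343 ± 299 (n = 8) in agonist tumors, a log2 fold change of 2.68 ± 0.53 (SE, adjusted p = 0.00276), and lay above the sham mean in 8 of 8 agonist libraries.

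Of the 689 genes tested with limma, 490 were higher and 5 lower after agonist at an adjusted p under 0.05. Without agonist replicates 6, 7 and 8, the only libraries written with 2 decimals, the counts were 3 and 0, with 5 in place of 8 agonist libraries, while the panel median was 0.67 and 333 genes had an unadjusted p under 0.05. In that setting 20 of 29 lists were higher, with T cell markers at a median of 1.22 against 1.51, and 0 lists passed with TMM scaling. The median log2 fold change of all tested genes was 0.98 under the authors' scaling and 0.13 with TMM scaling. TMM sets this median near 0 by construction, so it cannot show how much of the rise depends on the authors' scaling. The recovered totals before scaling were 418457 in agonist and 302789 in wild-type sham libraries on average (exact permutation adjusted p = 0.0552). With TMM scaling 69 genes were higher and 114 lower, and 69 of the 490 and all 5 of the lower genes were among these in the direction first called, while 10 of the 490 were called lower. Higher genes thus made up 99% of the calls under the authors' scaling and 37.7% with TMM. Each fold change below can be set against the panel median of 0.98.

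Among T cell markers, Cd4, the helper T cell coreceptor, rose by 2.22 ± 0.44 (log2, SE; adjusted p = 0.00276; 8 of 8 libraries above the sham mean) and Cd3d of the T cell receptor complex by 1.56 ± 0.31. The list passed the directional fry test (adjusted p = 0.00105) and also with TMM scaling (median 0.69, adjusted p = 0.00515). All 14 calls stood when adjusted over the list alone. A competitive camera test against the other genes gave an adjusted p of 0.0115 with a preset correlation, and adjusted p = 0.991 with an estimated correlation, the value of each list after agonist other than proliferation (adjusted p = 0.0733). The 5 tested regulatory T cell markers rose as well, 5 of 5 also when adjusted over the list alone, with Ccr8 up by 1.73 ± 0.35 and Ctla4, an inhibitory receptor, by 1.22 ± 0.28. That list passed under both scalings (adjusted p = 0.0012, and 0.0383 with TMM). With TMM 2 of its 5 genes were higher, and Ctla4 stood at 0.37 (limma adjusted p = 0.177). Without agonist replicates 6 to 8 the count was 0.

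Among NK cell markers, Ncr1, which encodes the activating receptor NKp46, rose by 2.25 ± 0.49 and Klrc1, an NKG2 receptor gene, by 2.05 ± 0.38. Klra7 rose by 2.35 ± 0.58, but its probe belongs to a family of near-identical Ly49 genes and its identity is uncertain. The list passed under both scalings (adjusted p = 0.00115, and 0.0153 with TMM), and 11 members passed when adjusted over the list alone. The cytotoxic genes Gzma and Gzmb, which encode granzymes, rose by 2.40 ± 0.57 and 1.97 ± 0.44, and Eomes, a transcription factor of cytotoxic lymphocytes, by 1.55 ± 0.33. All 12 tested effector genes also passed when adjusted over the list alone, and the list passed under both scalings (adjusted p = 0.00105, and 0.00645 with TMM). With TMM 5 of the 12 effector genes were higher, and without the agonist libraries written with 2 decimals 0 were. Il2rb, a subunit of the receptor for interleukins 2 and 15, rose by 2.16 ± 0.50.

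T cell attracting chemokines rose in 9 of 14 cases (9 adjusted over the list alone), by a median of 1.43, and the list passed under both scalings (adjusted p = 0.00105, and 0.0225 with TMM). Besides Ccl4, Cxcl9, an interferon-gamma induced chemokine, rose by 2.33 ± 0.69 (adjusted p = 0.00769), from 268 ± 270 (SD, n = 9) to 1347 ± 982 (n = 8) and in 7 of 8 libraries above the sham mean, but at 1.46 with TMM it did not pass (adjusted p = 0.0958). Ccl17 rose by 1.72 ± 0.31 and Ccl20, outside the list, by 2.20 ± 0.47.

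Interferon-stimulated genes rose in 29 of 31 cases, and in 29 adjusted over the list alone, with a median log2 fold change of 1.33 (fry adjusted p = 0.0014). Gbp5, a guanylate binding protein, rose by 2.05 ± 0.47, Ifih1, the RNA sensor MDA5, by 1.45 ± 0.32, and Irf1 by 1.25 ± 0.25. This list was not past the threshold once the panel was rescaled with TMM (median 0.47, adjusted p = 0.187). The same held for the antigen presentation lists. MHC class I genes rose in 14 of 14 cases (14 adjusted over the list alone), with Tap1, a peptide transporter, at 1.35 ± 0.31 and H2-K1 at 1.53 ± 0.37, and had a TMM adjusted p of 0.119. MHC class II genes rose in 8 of 9 cases (9 adjusted over the list alone), with H2-Ab1 at 1.58 ± 0.41 and Cd74, the invariant chain, at 1.47 ± 0.39, and had a TMM adjusted p of 0.238. Cytosolic nucleic acid sensing genes rose in 17 of 18 cases and interferons and their receptors in 7 of 8, with the same counts adjusted over the list alone and TMM adjusted p-values of 0.348 and 0.387. Ifnar1 and Ifnar2, the type I interferon receptor, rose by 0.80 ± 0.21 and 0.84 ± 0.22, but stood at -0.08 and -0.03 with TMM.

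Other immune lists rose by medians between 0.73 and 1.28 under the authors' scaling and passed the fry test there, with none past the threshold with TMM, where the alternative macrophage and mast cell medians turned to -0.14 and -0.11. Complement genes rose in 18 of 22 cases, led by C3 at 2.18 ± 0.49, C1s1 at 2.16 ± 0.59 and C2 at 1.96 ± 0.46. Without agonist replicates 6 to 8 the complement median moved from 1.28 to 0.79. There 0 of 22 genes were called, although the list passed (fry adjusted p = 0.0462). B and plasma cell markers rose in 7 of 9 cases, with Cd22 at 2.05 ± 0.49 and Cd79b at 1.97 ± 0.41, both at sham means under 10. Genes this low in sham can pass the filter through the libraries where they are high, which favors calls of higher. Co-stimulatory genes rose in 8 of 12 cases (Cd40 at 1.51 ± 0.29, Cd86 at 1.31 ± 0.28), and co-inhibitory checkpoint genes in 10 of 14 (Lag3 at 1.63 ± 0.37, Pdcd1 at 1.45 ± 0.35). Dendritic cell markers rose in 8 of 10 cases (Irf4 at 1.55 ± 0.33, Irf8 at 1.35 ± 0.30), macrophage and monocyte markers in 13 of 17 (Csf1r at 1.48 ± 0.35, Cybb at 1.41 ± 0.34) and neutrophil markers in 8 of 12 (Camp at 1.83 ± 0.45, Fcgr4 at 1.36 ± 0.32). Inflammatory cytokine and NF-kB genes rose in 15 of 22 cases (Ltb at 1.64 ± 0.37, Il18 at 1.18 ± 0.27), leukocyte adhesion molecules in 10 of 14, alternative macrophage activation genes in 7 of 13 and platelet and red cell markers in 2 of 4. Mast cell markers rose in 3 of 5 cases, with Kit at 0.73 ± 0.24 and Tpsab1, a tryptase, at 0.76 ± 0.28, which stood at -0.11 and -0.07 with TMM, and Tpsab1 did not pass without agonist replicate 6. The counts adjusted over the list alone were 19 for complement, 9 for B and plasma cells, 14 for macrophages and monocytes and 14 for inflammatory cytokines, and equal to those given for the other lists of this paragraph.

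Markers of cells other than leukocytes moved in the same libraries. Endothelial markers rose in 9 of 14 cases by a median of 0.75 (fry adjusted p = 0.00917), with Vwf, von Willebrand factor, at 1.07 ± 0.29 and Kdr, a VEGF receptor, at 1.17 ± 0.36. Fibroblast and pericyte markers rose in 5 of 10 cases by a median of 1.01 (adjusted p = 0.0206), or 0.65 without agonist replicate 8, where 5 genes held 34.2% of the signal, with the collagen gene Col1a1 at 1.80 ± 0.62 and Pdgfrb at 1.07 ± 0.35. Epithelial markers rose in 5 of 8 cases and fell in 1 (fry adjusted p = 0.00213), with Muc1, a surface mucin, at 0.82 ± 0.24, or -0.02 with TMM. Angiogenic factors and receptors rose in 4 of 10 cases (adjusted p = 0.00336) and had a median of 0.51, which turned to -0.36 with TMM. The endothelial median turned to -0.12 with TMM, and those of fibroblasts and epithelium stood at 0.14 and 0.08, with none of the 4 lists past the threshold. All 4 counts were the same adjusted over the list alone.

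The 5 lower genes were Birc5, Cd9, Dusp6, Fez1 and Tnfrsf12a. Birc5, which encodes survivin and is expressed in dividing cells, fell by 0.40 on the log2 scale (SE 0.14, adjusted p = 0.014), from 223 ± 12.6 (SD, n = 9) to 171 ± 33.6 (n = 8), and none of the 8 agonist libraries lay above the sham mean. Cd9, Dusp6, Fez1 and Tnfrsf12a fell with values of -0.66 ± 0.27, -0.55 ± 0.24, -0.47 ± 0.20 and -0.44 ± 0.16, and without 1 library Dusp6 no longer passed in 14 of 21 cases (-0.35 without agonist replicate 8), Fez1 in 12 and Cd9 in 9. The number of lower genes was 2 without sham replicate 6, 7, 8 or 9 or agonist replicate 1, 6, 7 or 8, 3 without sham replicate 3 or 5, 8 without agonist replicate 2 and 9 without agonist replicate 5. Of 6 proliferation genes 3 rose and 1 fell, also adjusted over the list alone, and the list did not pass under the authors' scaling (median 0.14, adjusted p = 0.218) but was lower with TMM (median -0.73, adjusted p = 0.0155). Cdk1, a mitotic kinase, and the cyclin gene Ccnd3 rose by 0.63 ± 0.20 and 0.74 ± 0.25, but stood at -0.20 and -0.13 with TMM. Apoptosis genes rose in 8 of 13 cases (8 adjusted over the list alone, fry adjusted p = 0.0012), with the death receptor Fas at 1.26 ± 0.30 and the kinase Ripk2 at 0.59 ± 0.16. The median of that list turned from 0.43 to -0.43 with TMM (adjusted p = 0.0153). There 0 of 13 apoptosis genes were higher and 6 lower, and Fas stood at 0.40 and Ripk2 at -0.27. Monocyte and neutrophil attracting chemokines did not pass (4 of 15 higher, 0 adjusted over the list alone with limma, fry adjusted p = 0.054).

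**Figure D1:**
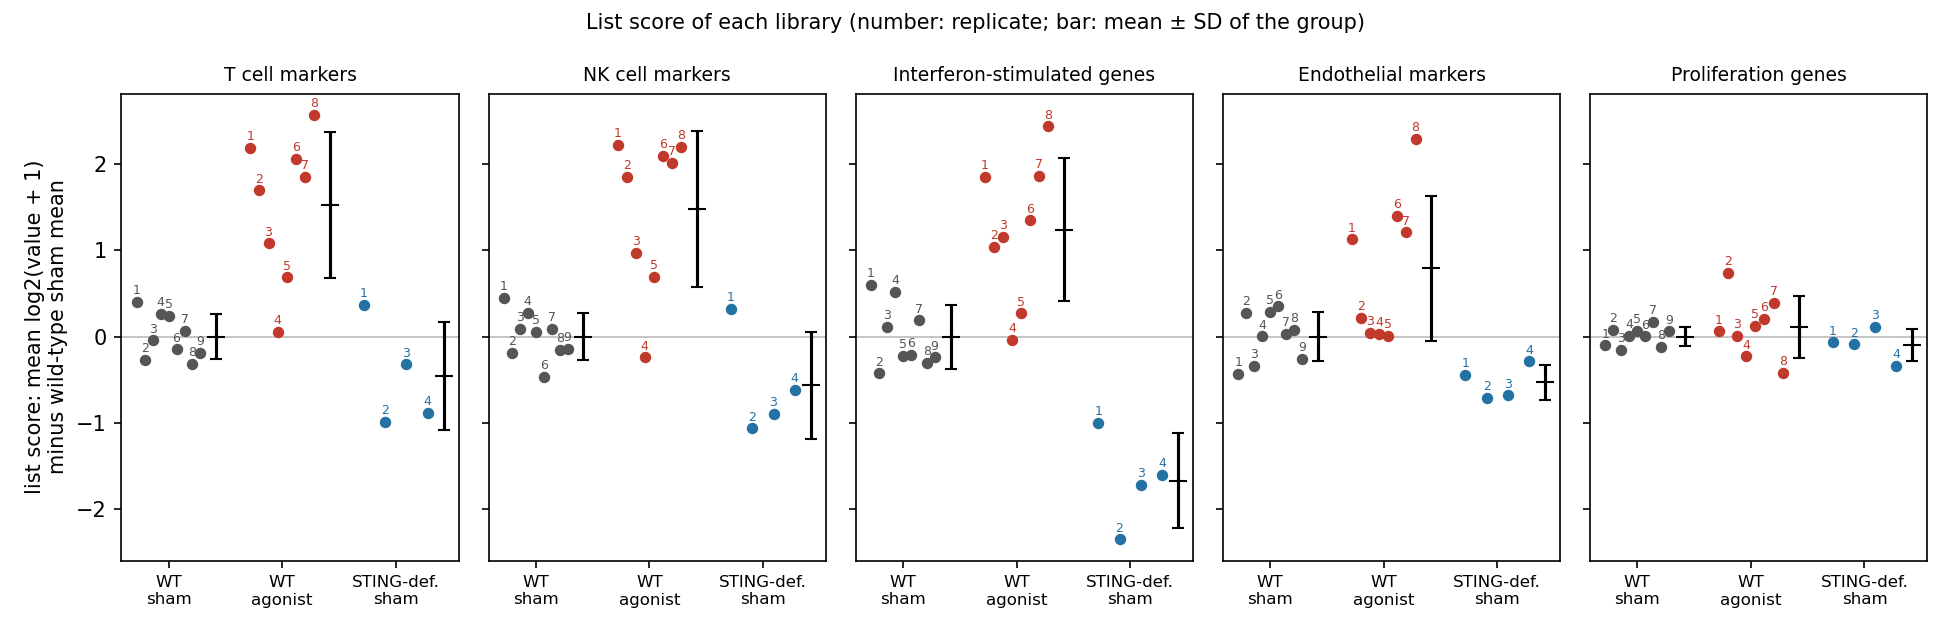
List score of each library, the mean log2(value + 1) of the list's tested genes minus the wild-type sham mean, for 5 lists. Each point is a library with its replicate number and the bars are mean ± SD of the 9 wild-type sham, 8 wild-type agonist and 4 STING-deficient sham libraries. Agonist replicate 4 lies within the sham points in all 5 panels except proliferation, and the STING-deficient libraries lie below all sham libraries for interferon-stimulated genes.

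The agonist libraries differed among themselves. The mean score over all tested genes, against the wild-type sham mean, was 1.39, 1.35, 0.47, -0.11, 0.19, 1.27, 1.23 and 1.60 in agonist replicates 1 to 8, against -0.17 to 0.15 in the 9 sham libraries. Agonist replicates 1 to 8 lay above the highest sham library in 28, 25, 17, 0, 7, 28, 28 and 27 of the 29 lists. Agonist replicates 6, 7 and 8 are the only 3 libraries written with 2 decimals in the matrix, all of 1 group, and leaving them out was a choice made after seeing the data. The comparison of 5 agonist with 9 sham libraries then called 3 of the 689 genes higher and 0 lower with limma, 333 having an unadjusted p under 0.05. The genes called included Ccl17 at 1.36 and Cxcr3 at 1.20, the last, a chemokine receptor of activated T cells, named after its value was seen. With the filter on low values applied anew, which left 597 genes, 0 were called in either direction. In the same 14 libraries the T cell, NK cell and cytotoxic lists had medians of 1.22, 1.13 and 1.22 and each a fry adjusted p of 0.0256, as had the epithelial (median 0.55) and apoptosis lists (median 0.29). The endothelial (0.40, adjusted p = 0.104), fibroblast (0.30, adjusted p = 0.248) and macrophage lists (0.40, adjusted p = 0.0775) did not pass, nor did the alternative macrophage, angiogenic, mast cell, platelet, proliferation and monocyte and neutrophil chemokine lists. In all, 20 of 29 lists were higher there, or 15 with the filter applied anew. With TMM scaling and without the 3 libraries, 0 of 29 lists and 0 genes passed, and the T cell, NK cell, cytotoxic and regulatory T cell lists had medians of 0.62, 0.52, 0.62 and 0.47 with adjusted p-values of 0.133, 0.164, 0.133 and 0.337.

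The second comparison asks what host STING deficiency changed in sham-injected tumors. Interferon-stimulated genes were lower in STING-deficient hosts, with 17 of 31 tested members lower, 22 adjusted over the list alone, and none higher. The median of the list was -1.59 on the log2 scale, a level of 0.331 times that of wild-type sham tumors. Ifit1, an interferon-induced protein that binds viral RNA, fell by 3.29 (SE 0.38, adjusted p = 1.12e-05), from 184 ± 53.5 (SD, n = 9) to 20 ± 10 (n = 4), and all 4 deficient libraries lay below the sham mean.

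Other members fell by similar amounts. Ifit3 fell by 3.33 (SE 0.67), Ifi44 by 3.27 (SE 0.49), Rsad2, the antiviral enzyme viperin, by 3.24 (SE 0.51), Isg15 by 2.92 (SE 0.47), Irf7, the transcription factor that amplifies type I interferon, by 2.89 (SE 0.54), Cmpk2 by 2.88 (SE 0.37) and Oasl1 by 2.61 (SE 0.61). Of the cytosolic sensing list, Ifih1 fell by 1.59 (SE 0.40) and Zbp1 by 1.83 (SE 0.49), both also members of the interferon list. Without 1 library the call of Zbp1 was lost in 13 of 21 cases, that of Ifih1 in 7 and that of Oasl1 in 3, the last without STING-deficient replicate 2, 3 or 4. The chemokines Cxcl10 and Cxcl5 fell by 2.23 (SE 0.60, adjusted p = 0.0479) and 1.65 (SE 0.45, adjusted p = 0.0496), and were the only calls outside the interferon list. For Cxcl10 1 of 4 deficient libraries lay above the sham mean and for Cxcl5 0 of 4, and their calls were lost without 1 library in 16 and 13 of 21 cases. In all, 19 of 689 genes were lower and 0 higher with limma, with 64 genes at an unadjusted p under 0.05, and 18 of the 19 were also lower with TMM. The panel median was -0.28, or -0.02 with TMM. DESeq2 on the recovered counts called 25 lower and 0 higher, and edgeR 10 lower and 0 higher.

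The other 28 lists did not pass the fry test under sham, with adjusted p-values from 0.297 to 0.907. T cell markers had a median of -0.43 and NK cell markers of -0.43 (both adjusted p = 0.392), each -0.75 without STING-deficient replicate 1 and -0.21 and -0.32 without replicate 2, macrophage and monocyte markers of -0.02 (adjusted p = 0.817) and MHC class II genes of 0.03 (adjusted p = 0.907). Cd2, Cd3g and Klrd1 of T and NK cells stood at 57.6 ± 7.9 (SD, n = 4), 31 ± 18.2 and 114 ± 92.5 in deficient tumors against 77 ± 23 (n = 9), 34.4 ± 11.7 and 141 ± 40.4, with adjusted p-values of 0.736, 0.882 and 0.659. Of the antigen presentation genes, H2-D1 stood at 3296 ± 1547 against 4197 ± 785 (adjusted p = 0.659), H2-T23 at 635 ± 355 against 1106 ± 405 (adjusted p = 0.507) and Cd74 at 2812 ± 2736 against 1702 ± 779 (adjusted p = 0.863). Neutrophil markers had the lowest median after the interferon list, -0.97 (adjusted p = 0.297), and S100a8, a neutrophil calcium binding protein, stood at 1573 ± 454 against 4429 ± 2370 (adjusted p = 0.279). Lyz2 stood at 10165 ± 2603 against 6416 ± 1832 (adjusted p = 0.652), Ifnar1 at 361 ± 44.6 against 382 ± 41.9 (adjusted p = 0.935) and Fcer1a, a mast cell receptor gene, at 96.8 ± 50 against 110 ± 31.3 (adjusted p = 0.796). Cxcl9 stood at 459 ± 634 against 268 ± 270, with a fitted log2 change of -0.13 (adjusted p = 0.978), -1.12 without STING-deficient replicate 1 and 0.60 without replicate 2, so that no direction can be read. Cd74 had a fitted change of 0.33, or -0.26 without STING-deficient replicate 1, and the class II median was -0.41 without it. Of the sensing list 2 of 18 genes fell (3 adjusted over the list alone), and of each chemokine list 1 fell (1 adjusted over the list alone).

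The interferon list passed the fry test (adjusted p = 0.0103) and with TMM scaling (median -1.34, adjusted p = 7.53e-05). With camera its adjusted p was 2.27e-32 at a preset correlation, and adjusted p = 0.111 with an estimated correlation. Without STING-deficient replicate 2 the list's median was -1.31 with an adjusted p of 0.0881, and the count of lower genes was 8 without STING-deficient replicate 2 or 3, 9 without replicate 4, and 10, 11 and 12 without sham replicate 1, 4 and 7. Fitted with the sham groups alone, where the wide spread of the agonist libraries does not enter, the comparison called 80 genes lower and 2 higher, and 10 lists lower.

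The third comparison, named in the series description, sets agonist-treated wild-type tumors against STING-deficient sham tumors and so changes treatment and host genotype together. Interferon-stimulated genes had the highest median of the 29 lists, 8.23-fold higher, with 31 of 31 tested members higher (31 adjusted over the list alone). Ifit3 was 5.01 ± 0.68 higher (log2, SE; adjusted p = 1.7e-05), at 1599 ± 1954 (SD, n = 8) against 27.5 ± 11 (n = 4), and Ifit1 4.26 ± 0.39 higher, at 376 ± 150 against 20 ± 10. All 8 agonist libraries lay above the STING-deficient mean for both genes. T cell, NK cell and cytotoxic lists were 4.34-fold, 3.86-fold and 4.41-fold higher by their medians.

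Rsad2, Ifi44, Oasl1, Irf7, Isg15 and Cmpk2 were higher by 4.58 ± 0.52, 4.57 ± 0.50, 4.54 ± 0.62, 4.54 ± 0.55, 4.28 ± 0.48 and 3.94 ± 0.37. The sensors Zbp1 and Ifih1 were higher by 3.38 ± 0.50 and 3.04 ± 0.40. Chemokines followed, with Cxcl10 at 3.83 ± 0.61 and Ccl4 at 3.42 ± 0.67, and 10 of 14 T cell attracting chemokines and 9 of 15 monocyte and neutrophil attracting ones were higher (10 and 7 adjusted over the list alone). Among T cell markers 15 of 15 were higher, with Cd3d at 2.17 ± 0.39, and among NK cell markers 12 of 12, with Klrc1 at 2.47 ± 0.47, Klrd1 at 2.05 ± 0.40 and the uncertain Klra7 at 4.13 ± 0.74. Cytotoxic effector genes were higher in 11 of 12 cases, with Gzmb at 2.72 ± 0.55. All 14 tested MHC class I genes were higher, with Nlrc5, their transactivator, at 3.21 ± 0.61 and Tap1 at 2.30 ± 0.39, as were 9 of 9 of class II. The counts of the T cell, NK cell, cytotoxic and both antigen presentation lists were the same adjusted over the list alone. The class II count depended on the setting. With TMM 0 of 9 class II genes were higher (median 0.002, fry adjusted p = 0.914), and in the fit of the compared groups alone also 0. Without the agonist libraries written with 2 decimals the class II count was 1.

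Neutrophil markers were higher in 11 of 12 cases by a median of 2.04, with Lcn2, lipocalin 2, at 3.11 ± 0.61, Camp at 2.86 ± 0.56 and Fcgr4 at 2.24 ± 0.41. Of 14 checkpoint genes 12 were higher, among them Cd274, which encodes PD-L1, at 2.78 ± 0.57 and Ctla4 at 1.89 ± 0.35. Fcgr1 was 2.07 ± 0.36 higher, and the endothelial genes Kdr and Vwf 2.13 ± 0.45 and 1.63 ± 0.37, in a list with 12 of 14 members higher. Adjusted over the list alone, 11 neutrophil, 12 checkpoint and 13 endothelial genes were higher. Muc1 and Tpsab1 were 1.33 ± 0.30 and 1.31 ± 0.36 higher. Tmem173, Ifnar2, Fcer1a and Ccnd3 were higher by 0.95 ± 0.37, 1.14 ± 0.28, 0.78 ± 0.32 and 0.99 ± 0.32, but stood at -0.17, 0.00, -0.36 and -0.15 with TMM. Fcer1a no longer passed without 1 library in 5 of 21 cases, and Tmem173 without STING-deficient replicate 2, 3 or 4.

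Other lists followed. Complement genes were higher in 16 of 22 cases (17 adjusted over the list alone), dendritic cell markers in 9 of 10 (10) and mast cell markers in 2 of 5 (1), while fibroblast genes were higher in 6 of 10 cases and lower in 1 (fry adjusted p = 0.0255, not passed without STING-deficient replicate 2 or 3). The remaining counts were the same adjusted over the list alone, namely 15 of 18 sensing, 8 of 8 interferon and receptor, 18 of 22 inflammatory cytokine, 12 of 14 adhesion, 10 of 12 co-stimulatory and 5 of 5 regulatory T cell genes, 5 of 9 B and plasma cell, 11 of 17 macrophage and 4 of 4 platelet markers, and 7 of 13 alternative macrophage, 8 of 10 angiogenic, 5 of 8 epithelial and 6 of 13 apoptosis genes. Of 6 proliferation genes 3 were higher and 1 lower (2 and 0 adjusted over the list alone). In the fit of all groups this was the only list of 29 that did not pass the fry test (adjusted p = 0.12). In the fit of the 2 groups alone the macrophage list (4 of 17 higher, fry adjusted p = 0.0543) and the fibroblast list (adjusted p = 0.0748) did not pass either. Without agonist replicates 6 to 8 both also failed to pass (fry adjusted p = 0.0886 and 0.133). Sigirr, Vim, Igf2r and Birc5 were the 4 lower genes, at -0.69 ± 0.24, -0.46 ± 0.19, -0.45 ± 0.20 and -0.40 ± 0.17, and without 1 library Igf2r no longer passed in 16 of 21 cases, Birc5 in 9 and Vim in 5. The number of lower genes was 1 without agonist replicate 1, 6 or 7 or STING-deficient replicate 2, 2 without sham replicate 9, agonist replicate 8 or STING-deficient replicate 4, 8 without agonist replicate 2 and 9 without agonist replicate 5.

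In total 507 genes were higher and 4 lower. Fitted with these 2 groups alone, where the spread of the wild-type sham libraries does not enter, 362 were higher and 0 lower. The score over all tested genes had an SD of 0.107 in wild-type sham, 0.64 in agonist and 0.242 in STING-deficient libraries. In that fit the interferon list had a fry adjusted p of 0.00268. The panel median was 1.35, or 0.24 with TMM scaling, where 133 genes were higher and 135 lower and 16 of the 507 were among the lower. Higher genes made up 99.2% of the calls and 49.6% with TMM. The interferon list passed under both scalings (fry adjusted p = 1.29e-05, and 5.39e-06 with TMM at a median of 1.92), and its camera result had an adjusted p of 1.26e-11 at a preset correlation and adjusted p = 0.938 with an estimated correlation, the value of each list here other than proliferation (adjusted p = 0.125). With TMM the T cell, NK cell, cytotoxic, regulatory T cell, chemokine, MHC class I, neutrophil, sensing and platelet lists were also higher, and apoptosis (median -0.63) and proliferation genes (median -1.0) lower, while the alternative macrophage, angiogenic, macrophage and mast cell medians turned to -0.32, -0.17, -0.19 and -0.36 without passing. Without agonist replicates 6, 7 and 8 the counts were 371 higher and 1 lower, or 322 and 1 with the filter applied anew.

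**Figure D2:**
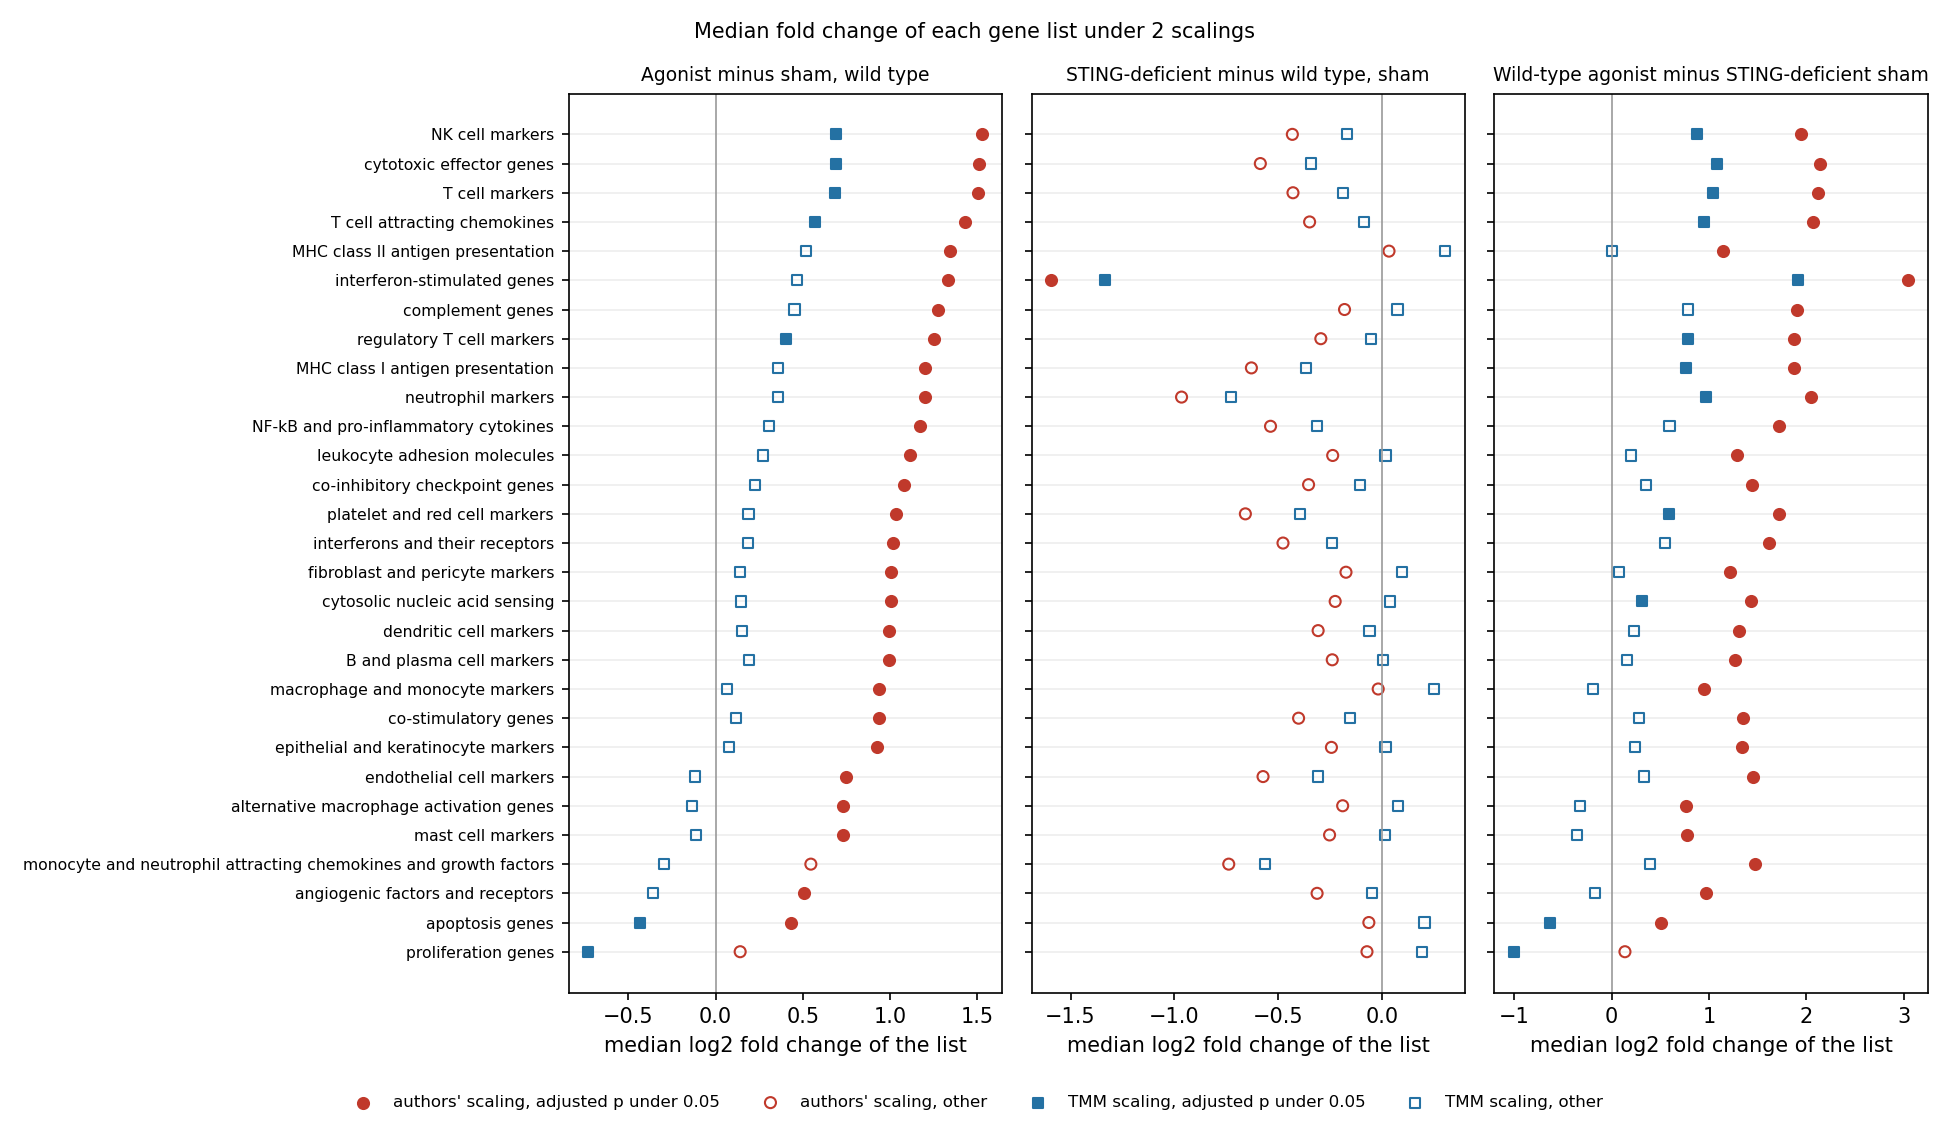
Median log2 fold change of each of the 29 gene lists in the 3 comparisons, with the authors' scaling (circles) and with TMM scaling (squares), filled where the fry adjusted p was under 0.05. Under TMM scaling the agonist medians shift down together, the T cell, NK cell and cytotoxic lists from 1.51, 1.53 and 1.51 to 0.69 each, and in the STING-deficient comparison only the interferon-stimulated list is filled.

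The fold changes of the agonist and of STING deficiency, both taken against the 9 wild-type sham libraries, had a Pearson correlation of -0.36 across 688 genes, which are not independent replicates. Of the 19 genes lower in STING-deficient tumors, 19 were among the 490 higher after agonist, where independent lists would share 13.5. With TMM scaling 3 genes had both calls against 1.9 for independent lists. The covariance was -0.11, against 0.03 on average in 100 simulated sets of unchanged groups with the same controls, a difference of -0.14. The correlation was -0.22 without STING-deficient replicate 2. The simulated correlations had a median of 0.27 and ran from -0.30 to 0.72. With the controls split at random into 5 for the agonist and 4 for the deficiency comparison, the correlation had a median of -0.40 over 100 splits.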

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

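Except for the counts over other splits of the libraries, the tests of explanations in this part were chosen only after the results they bear on had been seen.

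Most tested genes were higher in agonist libraries. The authors' scaling alone is argued against for the T cell markers, which kept an adjusted p of 0.00515 with TMM, although with TMM and without agonist replicates 6 to 8 the median moved from 0.69 to 0.62 and the adjusted p, with 5 in place of 8 agonist libraries, to 0.133. A lower share of tumor cells would raise all other cell types alike if tumor cells express none of their markers, which was not tested. As the sole cause it was examined, under that condition, with T and NK scores minus endothelial, fibroblast and mast cell scores. These lists were picked after their medians were seen, 1.51 and 1.53 against 0.75, 1.01 and 0.73. That choice favored a rise in the difference, so its p-value cannot decide. A factor common to a library nearly cancels in this difference, though less so for low probes. The difference was 0.73 higher in agonist than sham libraries (exact permutation p = 0.00633, 3 of 8 above the highest sham library). Without replicates 6 to 8 it was 0.79 higher (exact permutation p = 0.022). A lower share of tumor cells as the whole or a part of the cause stays open. Agonist replicates 6, 7 and 8, written with 2 decimals, are not the whole cause, since the other 5 differed from the 9 sham libraries by 0.66 in the score over all tested genes (exact permutation p = 0.018). For the whole panel, the medians of 0.128, 0.111 and 0.287 with TMM, median-of-ratios and total-count scaling are set near 0 by these scalings. They cannot tell the authors' scaling from a rise common to most genes. The authors' factor averaged 1.12 in agonist and 0.90 in sham libraries, too small a difference for a median rise of 0.98 (log2). Recovered totals before this factor averaged 418457 against 302789 (exact permutation adjusted p = 0.0552). The factor is thus not the whole cause, but whether another factor would be right was not tested. A response to the agonist stays open.

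Agonist replicates 3, 4 and 5 lay within or near the sham range in many lists. A swap that puts a strongly responding tumor among the sham libraries is argued against, since the highest sham score over all tested genes was 0.153. A swap with a weakly responding tumor would not show, as agonist replicates 4 and 5 scored -0.11 and 0.19. A single wrong label or a failed injection cannot be told apart from a tumor that did not respond, since replicate 4 lay inside the sham range in 23 of 29 lists, below it in 6 and above it in 0, and its 23 lists fall between the bounds set for the test. A varying response among treated hosts was not tested and stays open.

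Interferon-stimulated genes were lower in STING-deficient hosts. The authors' scaling is argued against by the fry TMM adjusted p of 7.53e-05. An equal loss of 6 leukocyte types is argued against by the list's score minus the mean of their scores. This difference was lower by -1.23 (exact permutation p = 0.0028, the smallest that 4 against 9 libraries allow). The list was picked as the only one past the threshold, which favored a low p. Mean scores in deficient libraries were -1.67 for this list, -0.94 for neutrophils and -0.07 for macrophages. Loss of a single leukocyte type was not tested. A single library is argued against as the source of the direction, since the median stayed at -1.305 or below whichever library was left out, but not as the source of the call, which without STING-deficient replicate 2 had an adjusted p of 0.0881. As a hypothesis found and tested on the same data, these values are consistent with a loss of host STING, but housing, litter and day of collection are not given in the sources used here and stay open.

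Other splits of the same libraries into groups of the same sizes were drawn, 100 per comparison with the real one included. For agonist against sham, 1 of 100 splits, the real one, called 495 genes or more, and the highest other called 419, while 2 of 100 called 27 lists or more, the highest other 28. For STING deficiency 1 of 100 called 19 genes or more, the highest other 7, and 1 of 100 called 1 list, the highest other 0. In the third comparison 1 of 100 called 511 genes or more, the highest other 479, and 1 of 100 called 28 lists or more, the highest other 27. For each of these 6 counts at most 2 of 100 splits reached the real one, under a share of 0.05. This argues against a chance division of the libraries but does not exclude it. The share was not adjusted for the 6 tests, and another split called more lists after agonist than the real one. How far the splits with 419 and 479 calls overlap the real groups was not tested.

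Single libraries stood apart from their group in 4 of 102 sets of library values and in 13 of 255 sets of gene values, where chance gives about 1 in 20. Agonist replicate 8 had a scaled total of 888241.7 against 538951.9 in the next library, a recovered total of 763976 against 464160, and 34.21% of its signal in the 5 highest genes against 24.84%. Agonist replicate 1 had a factor of 1.4143 against 1.1627 in the next. Agonist replicate 8 was also low for Tnfrsf12a at 184.9, Birc5 at 105.8 and Sigirr at 65.1, against 329.5, 152.9 and 137.2 in the nearest library. Among sham libraries, replicate 9 was low for Eomes at 5.3 and Kdr at 23.8, against 9.6 and 37.1, and replicate 1 for Fcer1a at 52.7 against 87.8. Among STING-deficient libraries, replicate 4 was high for Dusp6 at 3855.8 against 2859.6, replicate 2 low for Ifit1 at 5.4 against 22.1, and replicate 1 high for Oasl1 at 29.1 against 10. STING-deficient replicate 3 was high for S100a8 at 2254 against 1358.5 and low for Cd2 at 45.8 against 60. Tmem173 without the logarithm was high in sham replicate 5 at 77.8 against 59.8 and in STING-deficient replicate 1 at 69.4 against 46.6.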

How the results depend on the processing

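The edgeR test, the filter at 50, the floor at 20, the pseudocount of 10 and all settings without agonist replicates 6 to 8 were chosen after seeing the data; the other settings were planned. Not run were a factor from positive controls, a filter and a floor from negative controls, and a block for cartridge or scan date, since control probes were not used here and no cartridge or date is given in the sources used here. The stricter filter at 50 and no filter kept every count of genes and lists within 1.5 times, and DESeq2 every count of genes. The recovered counts, at 256573 or more per library, limit precision only for low probes, of which 61 were not tested.

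After agonist, where 490 genes were higher and 5 lower, TMM gave 69 and 114, median-of-ratios scaling 62 and 117 and total-count scaling 132 and 73, which by construction take out most of the rise common to the panel. Without agonist replicates 6 to 8 the counts were 3 and 0, and 0 and 0 with the filter applied anew, with TMM, or with both. Replicates 6 to 8 scored 1.27, 1.23 and 1.60 over all tested genes, near replicates 1 and 2 at 1.39 and 1.35. The libraries kept also include replicates 3, 4 and 5, at 0.47, -0.11 and 0.19. The effect of having fewer libraries was not told apart from that of these scores or of the 3 libraries left out, and the cause was not tested. Fits of the 2 groups alone gave 2 lower genes and edgeR 2, and the cause was not tested. Without each library in turn 433 to 539 were higher and 2 to 9 lower. For STING deficiency, with 19 lower and 0 higher, the fit of the 2 groups alone gave 80 and 2, the floor 12, the pseudocount of 10 11 and edgeR 10 lower; TMM without the 3 libraries gave 1 higher, and 1 with the filter applied anew. Leaving out each library gave 8 to 22 lower and 0 higher; the cause of these changes was not tested. In the third comparison, where 507 were higher and 4 lower, TMM gave 133 and 135, median-of-ratios scaling 116 and 153, total-count scaling 237 and 63, TMM without the 3 libraries 79 and 96, or 68 and 100 with the filter applied anew. Without the 3 libraries alone 1 was lower, and 322 were higher and 1 lower with the filter applied anew. The 2 groups alone gave 362 higher and 0 lower with limma. With edgeR 2 were lower, and leaving out each library gave 419 to 542 higher and 1 to 9 lower.

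Of 29 lists, 27 were higher after agonist. TMM gave 5 higher and 2 lower, median-of-ratios scaling 5 and 2, total-count scaling 5 higher, the filter applied anew without the 3 libraries 15, TMM without the 3 libraries 0, and 0 with the filter applied anew. Camera gave 1 higher and 2 lower with a preset and 0 higher with an estimated correlation, and leaving out each library 27 to 28. For STING deficiency, with 1 list lower, the 2 groups alone gave 10 lower, camera 2 with a preset and 0 with an estimated correlation, and leaving out each library 0 to 1, the 0 without STING-deficient replicate 2. In the third comparison, with 28 higher, TMM gave 10 higher and 2 lower, median-of-ratios scaling 9 and 2, TMM without the 3 libraries 5 and 2, or 4 and 2 with the filter applied anew, camera 2 and 1 with a preset and 0 higher with an estimated correlation, and leaving out each library 27 to 29. Camera sets a list against the other genes, so a rise common to the panel does not count there.

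The median of the interferon-stimulated genes after agonist, 1.33, did not pass with TMM (0.47, adjusted p = 0.187), median-of-ratios (0.45, adjusted p = 0.234) or total-count scaling (0.63, adjusted p = 0.0623), with TMM without the 3 libraries (0.24, adjusted p = 0.462; 0.19 and 0.595 with the filter applied anew), or with camera (at 1.33, adjusted p = 0.0897 with a preset and 0.991 with an estimated correlation). It ran from 1.10 to 1.54 without single libraries. Under deficiency it was -1.59, with an adjusted p of 0.111 by camera with an estimated correlation, and ran from -1.97 to -1.31, the last without STING-deficient replicate 2 (adjusted p = 0.0881). In the third comparison it was 3.04, with an adjusted p of 0.938 by camera with an estimated correlation, and ran from 2.76 to 3.42.

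The difference in scaled totals, 203200 after agonist, ran from 143791 to 235089 without single libraries, and from -24547 to -4314 under deficiency. In the third comparison it ran from 157868 to 249166, and without STING-deficient replicate 2 (207514) or 3 (208818) its exact permutation test had an adjusted p of 0.0727, with 3 libraries left in that group. The correlation of the fold changes of agonist and deficiency ran from -0.485 without STING-deficient replicate 1 to -0.225 without replicate 2, and was -0.287 and -0.293 without sham replicate 1 and 4.

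The reversals named next are of lists and genes that had passed the threshold. Among lists that had not, TMM also turned the medians of proliferation genes (-0.73) and of monocyte and neutrophil chemokines (-0.30) after agonist, of proliferation genes in the third comparison (-1.0), and of several lists under deficiency that passed with neither scaling. With TMM, after agonist, the direction reversed for the medians of the alternative macrophage (-0.14), angiogenic (-0.36), apoptosis (-0.43), endothelial (-0.12) and mast cell (-0.11) lists and for the genes Tmem173 (-0.013), Ripk2 (-0.27), Cdk1 (-0.20), Muc1 (-0.017), Ifnar1 (-0.075), Ifnar2 (-0.030), Kit (-0.11), Tpsab1 (-0.074) and Ccnd3 (-0.13). With TMM, in the third comparison, the direction reversed for the medians of the alternative macrophage (-0.32), angiogenic (-0.17), apoptosis (-0.63), macrophage (-0.19) and mast cell (-0.35) lists and for the genes Tmem173 (-0.17), Fcer1a (-0.35) and Ccnd3 (-0.14). With median-of-ratios scaling, after agonist, the direction reversed for the medians of the alternative macrophage (-0.15), angiogenic (-0.38), apoptosis (-0.45), endothelial (-0.13) and mast cell (-0.13) lists and for the genes Tmem173 (-0.029), Ripk2 (-0.28), Cdk1 (-0.22), Muc1 (-0.032), Ifnar1 (-0.092), Ifnar2 (-0.047), Kit (-0.13), Tpsab1 (-0.090) and Ccnd3 (-0.15). With median-of-ratios scaling, in the third comparison, the direction reversed for the medians of the alternative macrophage (-0.41), angiogenic (-0.26), apoptosis (-0.72), fibroblast (-0.007), macrophage (-0.27), mast cell (-0.44) and MHC class II (-0.084) lists and for the genes Tmem173 (-0.26), Ifnar2 (-0.084), Fcer1a (-0.44) and Ccnd3 (-0.23). With total-count scaling, after agonist, the direction reversed for the medians of the angiogenic (-0.20) and apoptosis (-0.27) lists and for the genes Ripk2 (-0.11) and Cdk1 (-0.049). With total-count scaling, in the third comparison, the direction reversed for the medians of the apoptosis (-0.28) and mast cell (-0.010) lists and for the gene Fcer1a (-0.010). With TMM and without agonist replicates 6 to 8, after agonist, the direction reversed for the medians of the alternative macrophage (-0.18), angiogenic (-0.23), apoptosis (-0.34), endothelial (-0.22), epithelial (-0.072), fibroblast (-0.33), macrophage (-0.23), mast cell (-0.18) and platelet (-0.038) lists and for the genes Tmem173 (-0.37), Kdr (-0.13), Pdgfrb (-0.014), Ripk2 (-0.092), Cdk1 (-0.12), Ifnar1 (-0.12), Ifnar2 (-0.029), Tpsab1 (-0.027) and Ccnd3 (-0.019). With TMM and without agonist replicates 6 to 8, in the third comparison, the direction reversed for the medians of the alternative macrophage (-0.059), angiogenic (-0.20), apoptosis (-0.57), epithelial (-0.040), fibroblast (-0.23), macrophage (-0.52), mast cell (-0.31) and MHC class II (-0.006) lists and for the genes Tmem173 (-0.54), Ifnar2 (-0.010), Fcer1a (-0.31) and Ccnd3 (-0.045). These scalings lower the fold changes of a comparison together, so that small rises can turn negative by construction, as with TMM alone; what leaving out the 3 libraries adds was not tested. Of the 119 named gene results and 84 other list results, leaving out single libraries reversed none that had passed the threshold. Of 2499 gene values 2368 kept their sign and side of the threshold, 126 lost their call and 5 that had not passed changed sign, namely Cxcl9 (4 times, up to 0.60) and Cd74 (1 time, -0.26) under deficiency. Of 1764 list values 1747 kept both, 2 lost their call, 6 gained one and 9 that had not passed changed sign, namely the MHC class II (5 times, down to -0.41), macrophage (3 times, up to 0.056) and fibroblast medians (1 time, 0.019) under deficiency. Without agonist replicates 6 to 8, 56 of 119 gene results kept their sign and side of the threshold and 63 lost their call, and 75 of 84 list results kept both and 9 lost their call.

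The replicate numbers showed no steady pairing of the libraries, which so few pairs cannot exclude. Deviations of libraries with the same number correlated at -0.202 to 0.288 for sham and agonist, where 1 of 8 correlated best with its own number. The range was -0.16 to 0.609 for the sham groups, the highest for replicate 1, and -0.082 to 0.189 for the third comparison. In each of these, 1 of 4 correlated best with its own number. With the replicate block 421 genes were higher and 3 lower after agonist, 11 lower under deficiency, and 401 higher and 2 lower in the third comparison, and 26, 1 and 26 lists passed.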

Other observations

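Both the fit and the lists of this part were planned, but the lists described here were picked after their results had been seen. With the 2 sham groups fitted alone, 9 lists other than the interferon-stimulated genes were lower in STING-deficient hosts. Neutrophil markers came first, with 5 of 12 genes lower and a median of -0.97 (fry adjusted p = 0.00301). Camera was not run in this fit, and in the fit of all groups each of these 9 lists had an adjusted p = 0.983 with an estimated correlation. S100a8 stood at 1573 ± 454 (SD, n = 4) against 4429 ± 2370 (n = 9), in 4 of 4 libraries below the sham mean, with a limma adjusted p of 0.0302 in this fit and 0.279 in the fit of all groups. Endothelial markers had 4 of 14 genes lower (median -0.57), interferons and their receptors 3 of 8 (median -0.48) and inflammatory cytokines 5 of 22 (median -0.54), each with an adjusted p of 0.0121. Sensing genes had 4 of 18 lower (median -0.23) and platelet and red cell markers 0 of 4 with limma (median -0.66), both at an adjusted p of 0.0259. Angiogenic factors had 1 of 10 lower (median -0.31) and co-stimulatory genes 0 of 12 with limma (median -0.40), both at 0.0352, and checkpoint genes 3 of 14 (median -0.35) at 0.0481. None of these 9 lists passed in the fit of all groups, with either scaling, where neutrophil markers had adjusted p-values of 0.297 and 0.186 with TMM. The median of all tested genes was -0.28 in this comparison, which is about the whole median of the angiogenic, checkpoint and sensing lists, at -0.03, -0.07 and 0.06 relative to it. With TMM in the fit of all groups the medians were -0.73 for neutrophil, -0.31 for endothelial and -0.40 for platelet markers, -0.31 for inflammatory cytokines, -0.24 for interferons and receptors, -0.16 for co-stimulatory, -0.11 for checkpoint and -0.05 for angiogenic genes, and 0.04 for sensing genes. Under the authors' scaling the angiogenic median was -0.49 without STING-deficient replicate 4, the checkpoint median -0.61 and -0.15 without replicate 1 and 2, and the co-stimulatory median -0.26 without replicate 2.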
